A study of Drosophila melanogaster with 16 samples.

How the data were processed

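The 16 libraries came from Drosophila melanogaster S2 cells, a cell line with properties of hemocytes, the phagocytic blood cells of the fly. Per the labels' protocols, cells were given heat-killed Staphylococcus aureus, harvested at 0, 0.5, 1 or 4 h, fixed with formaldehyde and digested with micrococcal nuclease (MNase) at either 200 U/ml, the heavy digest, or 40 U/ml, the light digest. MNase removes DNA that is not held by nucleosomes or other bound proteins. The mononucleosomal band was taken from an agarose gel, amplified by PCR and sequenced from both fragment ends, per the labels' protocols. Each of the 8 combinations of digest and time has 2 libraries, named A and B in the labels. No label says whether A and B came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

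The deposited files list the chromosome, start and end of 1 sequenced fragment per line, on the dm3 build, with no value column. Per the submitters' processing notes, cutadapt 1.7 and Bowtie2 2.1.0 were used and the build was dm3. The role and settings of these tools, the treatment of fragments that align to several places and the handling of PCR duplicates are not given in the sources used here. All counts below were therefore made from the deposited fragments and are not counts made by the authors. A fragment recovered from a repeated sequence may have been placed at one of several copies, which affects the heterochromatic scaffolds and any site of very high density. PCR copies cannot be told from separate molecules of the same ends, so identical fragments were also counted once as an alternative. The gel step limits which fragments were seen, and the files hold fragments of 42 to 500 bp.

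Fragment midpoints were counted in 5 kb bins along arms 2L, 2R, 3L, 3R, 4 and X, in 1-based dm3 coordinates. These bins took the place of windows at gene starts because gene coordinates of dm3 were not used here. For the same reason the planned gene lists, individual genes and the depth of nucleosome-depleted regions at gene starts were not analysed here. Bins with at least 10 fragments in at least 2 libraries were tested, 23655 of 24076. Counts were scaled by the trimmed mean of M-values and tested with limma voom, with 1 mean per group, all 16 libraries in the same fit and Benjamini-Hochberg adjustment over bins at 0.05. The comparisons were each later time against 0 h within each digest, the mean of both digests, heavy against light over the 4 times, and the difference between digests in the response to time. In each comparison the 5 bins of largest fold change per direction were named among those past the threshold and of the same sign in A and B. Where none passed, the 3 bins of smallest unadjusted p per direction were named as not passing. The text gives a selection of these. The error of a log2 fold change is the standard error (SE) from limma, and other errors are standard deviations (SD).

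Measures of 1 value per library were compared with exact two-sided tests. Heavy and light libraries of the same time and letter were compared by all 256 sign flips of the 8 pairs, which cannot give a p below 0.00781. Later times were compared with 0 h by all 256 choices of the time called 0 h in the 4 series of digest and letter. Shares of fragments were compared on the log2 scale and adjusted over the 3 compartments (arms, heterochromatic scaffolds and mitochondrial genome), or over 12 sequences. The main repeat length was the period, searched between 150 and 240 bp, of a damped cosine fitted to the distances between midpoints, from 120 to 960 bp. Because the labels do not say that the letters pair the samples, the digest labels were also permuted within each time without pairs, in 1296 arrangements. The groups, comparisons, bin filter, tests and naming rule were fixed before the data were examined. The ratio of density near the centromere end of an arm to the rest of the arm, the 100 kb bins, the tests by single sequence and the tests of fragment length between compartments were chosen after the data were seen.

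Libraries held 268620 to 8058782 fragments, 35960700 in all, which gave a median of 10 fragments per bin in the shallowest library and 313 in the deepest. The procedure was tested on simulated data, drawn for the 23655 bins from the means and depths of the real libraries with 50 bins changed per fold size. In the light digest at 4 h, 24% of bins changed 2-fold and 86% of bins changed 3-fold were recovered. In the heavy digest at 4 h these values were 72% and 96%, and for both digests together 94% and 98%. For heavy against light, 90% of bins changed 1.5-fold were recovered. Unchanged bins called in the same simulation numbered 5 for the heavy digest at 4 h and 8 for each of the others. A further 20 draws held no changed bin, and no comparison called more than 1 bin in any of them. All draws used the same overdispersion for every group and no difference between the letters A and B. Splitting the real libraries otherwise, over both digests at 4 h, called up to 379 bins. The simulated recovery and the calls without a change may therefore be too favourable at 4 h. The alternatives covered scaling, filters, bin size, fragment length, identical fragments, thinning to the smallest library, limma trend, library weights, a fit of a single digest, a replicate block, median fragment length as a term, robust moderation and leaving out each library. The count-based tests planned for a deposited count column were not run, because no deposited column holds counts, and the GC correction was not run for lack of a dm3 sequence. Software was R 4.3.3 with limma 3.58.1 and arrow 21.0.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.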

Results

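Nucleosome occupancy was mapped in S2 cells at 0, 0.5, 1 and 4 h after heat-killed Staphylococcus aureus was added, at 2 levels of MNase. Staphylococcus aureus is a Gram-positive bacterium, a class that flies sense mainly through the Toll pathway. The design asks where fragment density along the genome changes after stimulation, and which regions respond to the level of the nuclease. There were 16 libraries, 2 in each of 8 groups. Depth was uneven over time: the 0 h libraries held 299564 ± 43761 fragments in the light digest and 714922 ± 375521 in the heavy digest, and the 4 h libraries 7270516 ± 1114776 and 2964112 ± 2456157 (SD, n = 2 each). Within the 4 series of digest and letter, later libraries were 4.51-fold deeper than 0 h libraries on average, and deeper in 4 of 4 series (exact permutation test, p = 0.00781). Comparisons with 0 h are therefore mostly also comparisons of deep with shallow libraries, but heavy 1 h A held 735938 fragments, fewer than heavy 0 h A with 980455.

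Heavy digestion gave shorter fragments and smaller shares of the mitochondrial genome, chromosome 4 and the heterochromatic scaffolds. The median fragment on the arms was 113.2 ± 8.08 bp in the heavy digest and 130.2 ± 5.99 bp in the light digest (SD, n = 8 each). The difference of −17 ± 6.72 bp was seen in 8 of 8 pairs (exact sign-flip test, p = 0.00781, the smallest possible). Fragments of 50 to 100 bp, shorter than the DNA of a whole nucleosome, made up 36.2% ± 8.39 of the heavy and 24.4% ± 4.93 of the light libraries. Fragments of 120 to 180 bp made up 38.5% ± 7.39 and 49.8% ± 3.77. Both shares differed in 8 of 8 pairs (exact p = 0.00781 for each). Within the heavy digest the 0 h libraries lay furthest apart, at 98 and 123 bp.

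**Figure D1:**
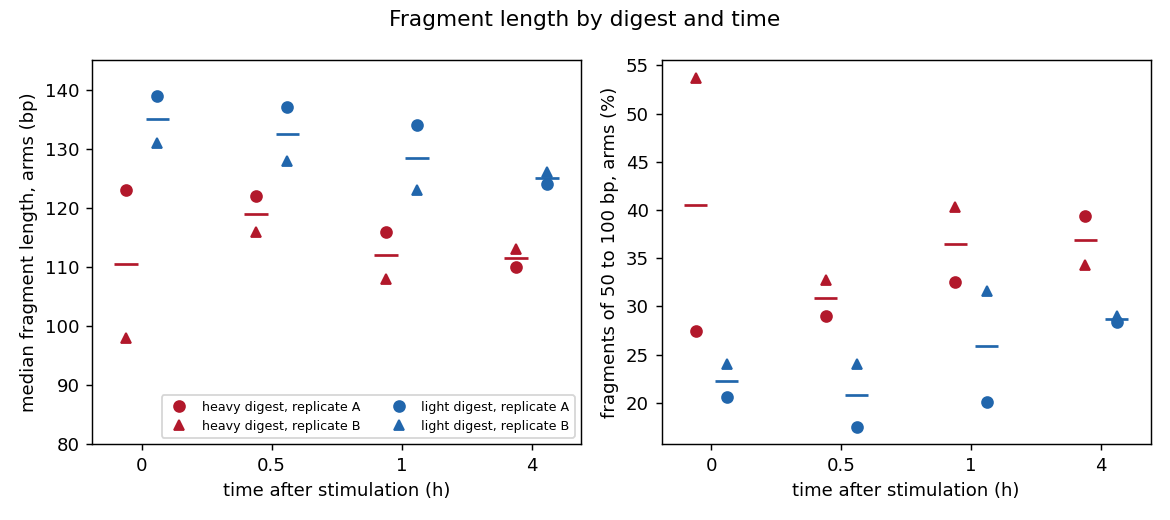
Median length of fragments on the arms in bp (left) and share of fragments of 50 to 100 bp in percent (right) against time after stimulation in h. Each point is 1 library, by digest and replicate letter, and bars are means of 2 libraries. Heavy libraries average 113.2 bp and light libraries 130.2 bp.

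The mitochondrial genome took 0.0694% ± 0.017 of heavy fragments and 0.374% ± 0.103 of light fragments (SD, n = 8 each). It was 5.33-fold higher in the light digest, in 8 of 8 pairs (exact test, adjusted p = 0.0117). Chromosome 4, a small chromosome rich in repeats and HP1, took 0.868% ± 0.0586 of heavy and 0.996% ± 0.057 of light fragments. Its log2 ratio of −0.20 had the same sign in 8 of 8 pairs (exact test, adjusted p = 0.0187 over 12 sequences). The heterochromatic scaffolds took 7.0% ± 0.583 and 7.63% ± 0.747, lower in the heavy digest in 7 of 8 pairs (exact test, adjusted p = 0.0234). That call was lost when identical fragments were counted once (exact test, adjusted p = 0.0781) and without pairs (adjusted p = 0.11). The arms took 92.9% ± 0.593 of heavy and 92.0% ± 0.767 of light fragments (exact test, adjusted p = 0.0117). Arms 2R and 3R were each 1.03-fold higher in the heavy digest in 8 of 8 pairs (exact test, adjusted p = 0.0187 for each).

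**Figure D2:**
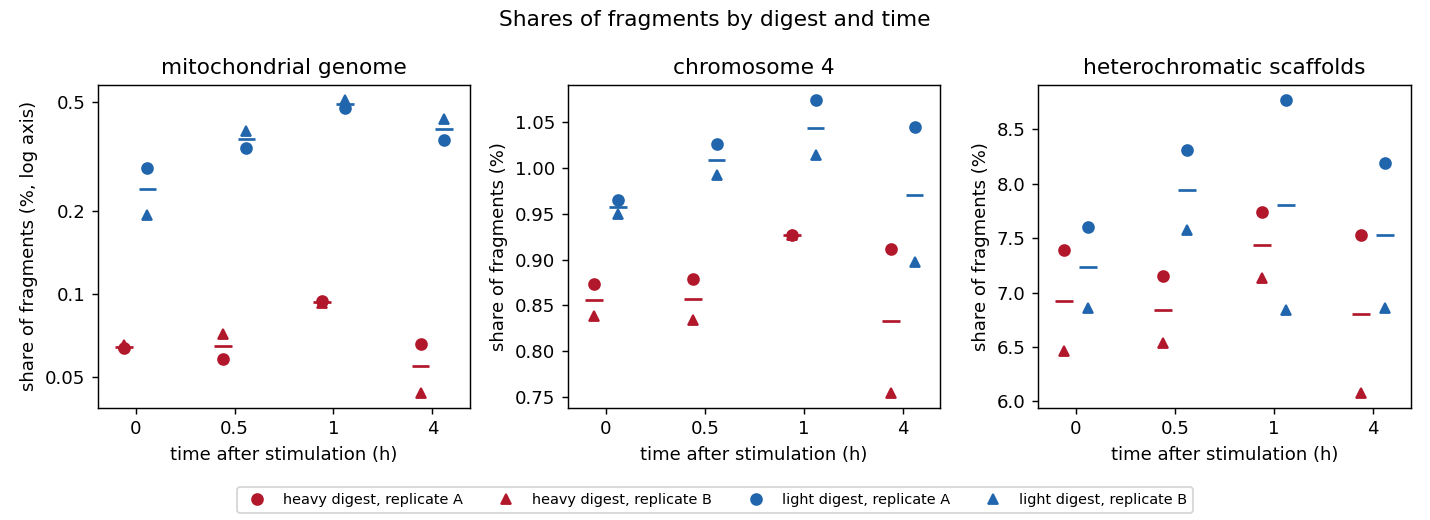
Share of all fragments in percent on the mitochondrial genome (log axis), chromosome 4 and the heterochromatic scaffolds against time after stimulation in h. Each point is 1 library and bars are means of 2. Light libraries exceed heavy libraries of the same time and letter in 8 of 8 pairs for the mitochondrial genome and chromosome 4, and in 7 of 8 for the scaffolds.

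Along the chromosomes, 975 of 23655 bins differed between the digests, 431 higher and 544 lower in the heavy digest (limma voom, adjusted p under 0.05). Chromosome 4 stood apart, with 51 of its 260 bins lower and 2 higher (19.6% and 0.769%), while 1.45% to 2.81% of the bins of each other arm were lower. In 100 kb bins, 11 of the 14 bins of chromosome 4 were lower. The 1 Mb nearest the centromere also held more bins lower in the heavy digest, 63 of 947 (6.65%) against 430 of 22448 (1.92%) on the rest of the 5 large arms. By arm these shares near the centromere were 10.9% on 2L, 7.89% on 2R, 8.81% on 3L, 2.03% on 3R and 3.43% on X. The density of that end relative to the rest of the arm was lower in the heavy digest on each of the 5 arms. Its log2 ratios were −0.11 on 2L, −0.14 on 2R, −0.13 on 3L, −0.06 on 3R and −0.07 on X, in 8 of 8 pairs except on 3L, with 7 of 8 (exact tests, adjusted p = 0.00977 on 4 arms and 0.0156 on 3L). On X, this ratio left out the densest bin, 21830001 to 21835000, which lies near the centromere. Without pairs, the call on X was lost (exact p = 0.0988).

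Differences of single bins were mostly small, with a median log2 fold change of 0.44 among the higher and −0.49 among the lower bins. The best supported of the named bins was 2L 4480001 to 4485000, where the heavy digest was higher by 0.83 on the log2 scale (SE 0.13, adjusted p = 1.4e-05, 1588 fragments over all libraries). Over all bins, the smallest adjusted p was at X 21830001 to 21835000, with a log2 fold change of −0.82 (SE 0.1, limma voom, adjusted p = 4.1e-08). The spread of that bin between libraries was unusually large, as described below. The bin X 1890001 to 1895000 was higher by 0.87 (SE 0.19, adjusted p = 0.0019) and 2R 14465001 to 14470000 by 0.84 (SE 0.23, adjusted p = 0.019). The lower bins with the largest changes were shallow. The bins 2L 21350001, 2L 21435001, 3L 24130001 and X 21020001 passed the filter on fragment counts through light libraries alone. Their selection therefore favoured a lower value in the heavy digest. On 2L, 21350001 to 21355000 had a log2 fold change of −2.01 (SE 0.43, adjusted p = 0.0019) on 65 fragments, and 21435001 to 21440000 had −1.59 (SE 0.37, adjusted p = 0.0053) on 84. On 3L, 24130001 to 24135000 had −1.86 (SE 0.39, adjusted p = 0.0018) on 92, and on X, 21020001 to 21025000 had −1.46 (SE 0.37, adjusted p = 0.012) on 69. On the distal side of 2L, 3205001 to 3210000 had −1.43 (SE 0.30, adjusted p = 0.0017) on 248. The higher bins 2L 2105001 to 2110000 (1.00, adjusted p = 0.045) and 2R 20615001 to 20620000 (0.94, adjusted p = 0.046) lay close to the threshold, and their calls were lost in 13 of 29 and 14 of 28 alternatives. The call of 2R 14465001 was lost in 7 of 29, with log2 fold changes of 0.23 to 1.25, among them without heavy 0 h A (adjusted p = 0.065), light 0 h B (0.45) or light 1 h B (0.11). That of X 21020001 was lost in 6 of 27, among them without heavy 0 h A (0.067), heavy 1 h B (0.11) or light 0 h A (0.051). That of 2L 21435001 was lost in 3 of 25, with −1.93 to −0.30, among them without light 0 h B (0.06), and that of X 1890001 in 2 of 30, among them without heavy 0 h A (0.077).

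The number of called bins depended on depth and on which libraries were used. It was 28 with every library thinned to the smallest, 40 with median fragment length as a term, which differs between the digests by design, 393 with limma trend, 341 with fragments of 120 to 180 bp only, and 2118 without the 0 h libraries. It fell to 310 without heavy 0 h A, 457 without heavy 1 h B, 382 without heavy 4 h B, 432 without light 0 h A, 290 without light 0 h B, 497 without light 0.5 h A and 599 without light 1 h B, and was 1689 without light 4 h B. The balance of directions also moved: higher bins outnumbered lower ones after thinning (20 and 8), with the length term (28 and 12), with fragments of 120 to 180 bp (208 and 133), with limma trend (217 and 176), and without heavy 0 h A (135 lower of 310) or heavy 1 h B (233 and 224), while 55 were higher and 235 lower without light 0 h B.

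**Figure D3:**
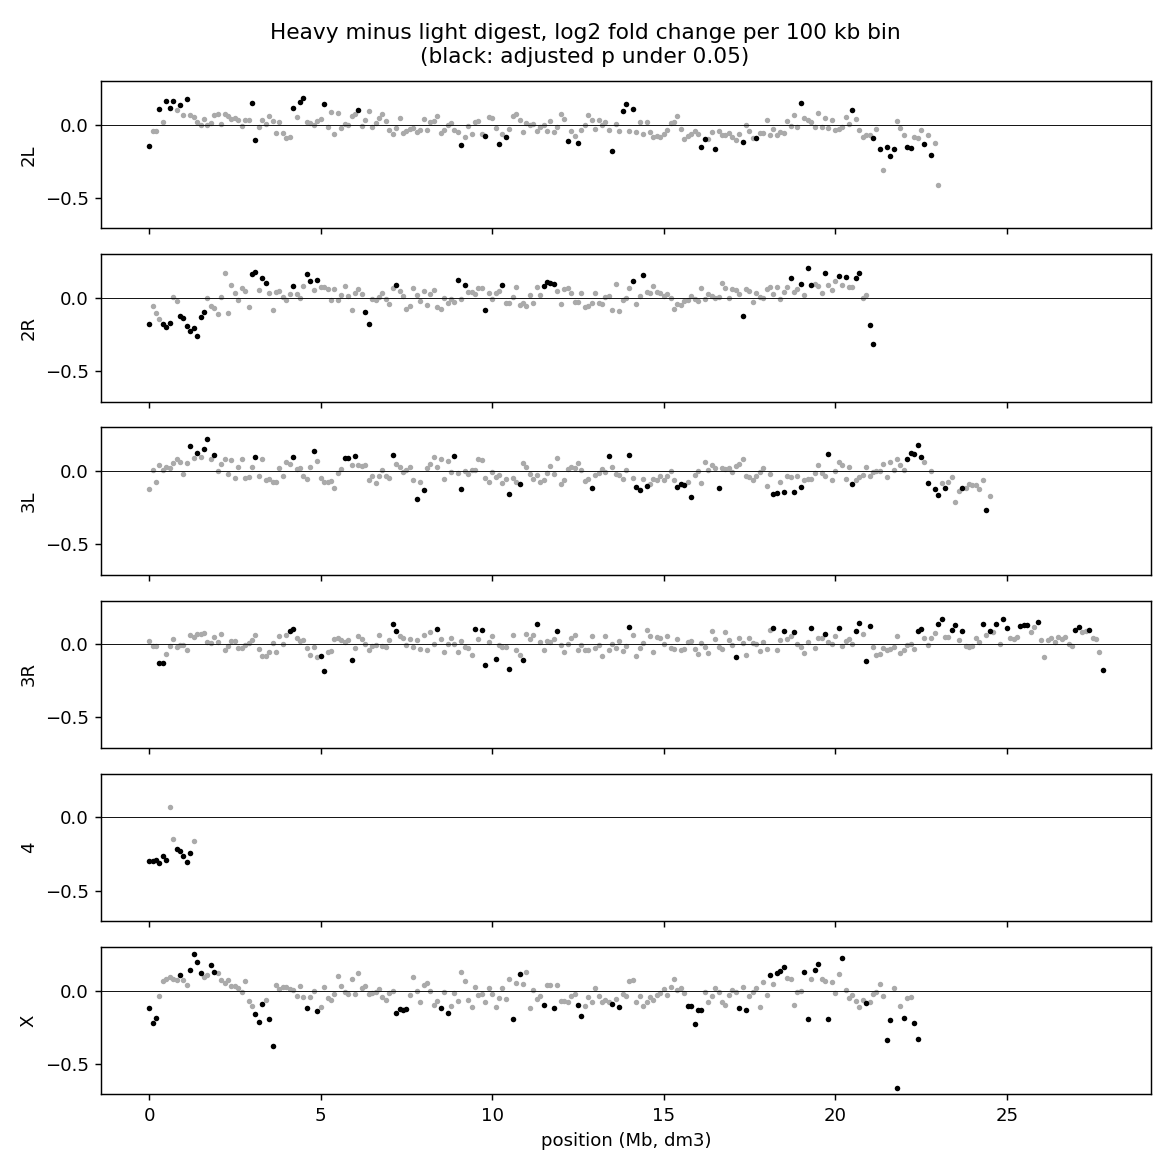
Log2 fold change of heavy against light digest in 100 kb bins against position in Mb on dm3, 1 panel per arm. Black points have an adjusted p under 0.05 by limma voom (119 higher and 129 lower of 1207). Values on chromosome 4 lie mostly below 0, as do those at the right end of 2L and the left end of 2R, which face the centromere. The outermost bins at the opposite ends of 2L and 2R also lie below 0.

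After stimulation, 2 bins fell in the light digest at 4 h, 1 on X and 1 on 2R, and no bin passed at any time in the heavy digest. In 20 simulated draws with no changed bin, 1 bin was called in 5 draws for the light digest at 4 h and in 1 draw for both digests at 4 h, so a single call can arise without a change. The direction at light 4 h depended on the filter: without a filter on low counts 2 bins were higher and 96 lower, and with at least 10 fragments in 8 libraries 12 were higher and 3 lower. The light 4 h count was 0 without light 0 h A, 5 without light 4 h A and 1 without light 4 h B. The bin on 2R, 1390001 to 1395000, held 81.6 ± 4.97 CPM (fragments per 1000000 on the arms after scaling) at 0 h, 35.2 ± 4.24 at 0.5 h, 39.3 ± 1.98 at 1 h and 35.6 ± 3.2 at 4 h (SD, n = 2 each). Its log2 fold change at 4 h was −1.24 (SE 0.25, adjusted p = 0.026). The values at 0.5 h (−1.26, adjusted p = 0.98) and 1 h (−1.06, adjusted p = 0.64) did not pass. The light 0 h libraries were the shallowest, with 247436 and 307188 fragments on the arms, so the 0 h values rest on few fragments. Each light comparison uses these same libraries, so the falls at the later times are not independent. In the heavy digest the same bin held 30.9 CPM at 0 h, and its value at 4 h was −0.44 (SE 0.28, adjusted p = 1). The call was lost without light 0 h A (adjusted p = 0.33), light 0 h B (0.70) or light 4 h B (0.11), and with fragments of 120 to 180 bp only (0.70), among 8 of 18 alternatives.

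The bin on X, 21830001 to 21835000, was the densest tested, and 99.4% of its 159103 fragments lay in the 1 kb from 21834001 to 21835000, which held 864 times the median of a 1 kb bin of X. In the light digest it took 13800 ± 4530 CPM at 0 h, 6080 ± 2660 at 0.5 h, 6650 ± 535 at 1 h and 4920 ± 2010 at 4 h (SD, n = 2 each). In the heavy digest it took 4310 ± 3290, 3970 ± 2600, 5760 ± 1210 and 4520 ± 3100. Its log2 fold change at 4 h was −1.48 in the light digest (SE 0.21, adjusted p = 2.2e-06) and −0.89 over both digests (adjusted p = 0.0033). These p-values rest on the moderation of the spread by limma: the residual SD of this bin was 19.1 times the median, its own SE was 0.73, and with robust moderation the adjusted p was 1. The call was also lost without light 0 h A (adjusted p = 0.30).

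**Figure D4:**
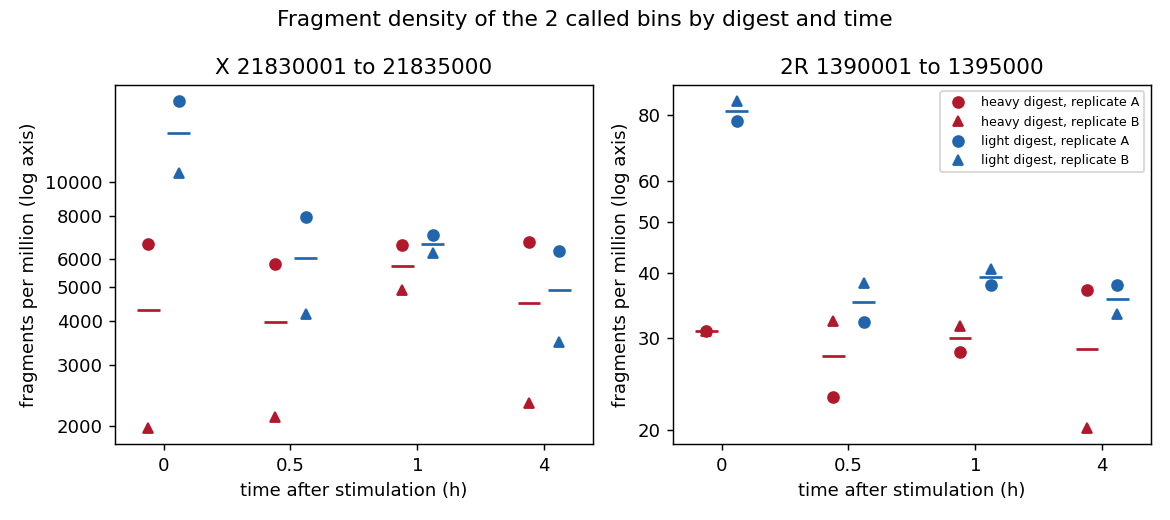
Fragment density in CPM (log axes) in the bins X 21830001 to 21835000 and 2R 1390001 to 1395000 against time after stimulation in h. Each point is 1 library and bars are means of 2. In both bins the light 0 h libraries lie above the light libraries of later times, while the heavy libraries of 0 h overlap those of later times.

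In the heavy digest, limma voom called 0 bins at 0.5, 1 and 4 h, with 906, 934 and 1167 bins at an unadjusted p under 0.05 (3.83%, 3.95% and 4.93%), and limma trend also called 0 at each time. With at least 10 fragments in 8 libraries, 1 bin passed at each time, as did 1 with a replicate block, and after thinning 1 passed at 1 h. The bin with the smallest p was 3L 11035001 to 11040000 at 4 h, with a log2 fold change of −1.19 (SE 0.25, adjusted p = 0.17, and 0.045 with a replicate block). At 0.5 h it was X 8735001 to 8740000, with −1.39 (SE 0.31, adjusted p = 0.59), and at 1 h it was 2L 825001 to 830000, with 0.99 (SE 0.26, adjusted p = 1). The last of these bins had 0.80 at 4 h (SE 0.25, adjusted p = 1).

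In the light digest, limma voom called 0 bins at 0.5 h and at 1 h, with 1014 and 1082 at an unadjusted p under 0.05, while limma trend called 188, 60 and 41 bins at 0.5, 1 and 4 h. Of these, 146, 58 and 41 were higher than at 0 h and 42, 2 and 0 lower, so limma trend kept neither of the 2 bins that fell at 4 h. With a replicate block, 2 bins passed at 0.5 h and 2 at 1 h. At 0.5 and 1 h, 5 and 7 bins passed with at least 10 fragments in 8 libraries, 2 and 3 without light 0 h B, and 1 each with identical fragments counted once, after thinning, with library weights and in a fit of a single digest, and at 0.5 h 1 passed without light 0.5 h A. The light 0 h libraries held a median of 10 and 12 fragments per bin. The bin X 7435001 to 7440000 held 12.3 and 0 CPM in the 0 h libraries and 38.5 and 27.1 at 0.5 h (log2 2.85, SE 0.73, adjusted p = 0.98). The bin 2R 13820001 to 13825000 held 12.3 and 6.55 at 0 h and 51.3 and 45.8 at 1 h (log2 2.16, SE 0.55, adjusted p = 0.64). In the other direction, X 8365001 to 8370000 held 57.6 and 58.9 at 0 h and 19.8 and 23.9 at 0.5 h (log2 −1.46, SE 0.37, adjusted p = 0.98), and 3L 6425001 to 6430000 held 57.6 and 88.4 at 0 h and 22.6 and 37.9 at 1 h (log2 −1.16, SE 0.28, adjusted p = 0.64). Over both digests limma voom called 0 bins at 0.5 h and at 1 h, with 986 and 1068 at an unadjusted p under 0.05 and 2 and 3 by limma trend. With a replicate block the counts at 0.5, 1 and 4 h were 1, 1 and 3. At 4 h limma voom called the bin on X and limma trend 0 bins. That count of 1 was 106 without a filter on low counts, 0 without heavy 0 h A, heavy 4 h B or light 0 h A, and 3 without heavy 0 h B, heavy 4 h A or light 4 h A. At 0.5 h 1 bin passed without heavy 0 h B, heavy 0.5 h A, light 0 h B or light 0.5 h A, and at 1 h 1 passed without light 0 h B.

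The response to time was not shown to differ between the digests in any bin: limma voom called 0 by its F test, with 392 at an unadjusted p under 0.05, and limma trend called 0. The count by limma voom was 4 with a replicate block. It was 1 with at least 10 fragments in 8 libraries, with identical fragments counted once, after thinning and with library weights, 1 without heavy 0 h A, heavy 0.5 h A, heavy 0.5 h B, heavy 4 h A or light 4 h A, and 2 without heavy 4 h B or light 4 h B. For the bins called in the light digest, the difference between digests at 4 h was 1.17 (SE 0.32) on X and 0.80 (SE 0.37) on 2R, with an adjusted p of 1 for each. Recovery of such a difference was not simulated. Within a digest at 4 h, 96% of simulated bins changed 3-fold were recovered in the heavy and 86% in the light digest, but 72% and 24% of those changed 2-fold.

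No measure of length or composition passed its test over time. The median fragment length of later libraries was −1.33 bp from that of 0 h (exact permutation test, p = 0.77), with 3.67 bp in the heavy and −6.33 bp in the light digest (difference of 10 bp, exact p = 0.184). Without heavy 0 h B it was −6.56 bp, and it lay above 0 without heavy 0 h A or light 0 h A (at most 0.667 bp). The mitochondrial share was 1.37-fold higher after 0 h, in 4 of 4 series (exact p = 0.0664, adjusted p = 0.152), and passed without heavy 4 h B (exact test, adjusted p = 0.0469). Without series its exact p was 0.0434, and 0.13 after adjustment. Its log2 ratio was 0.09 in the heavy and 0.81 in the light digest, a difference that did not pass (exact p = 0.164). The heterochromatic scaffolds were 1.04-fold higher in 4 of 4 series (exact test, adjusted p = 0.211), and the arms 0.996-fold (exact test, adjusted p = 0.152). The X chromosome took 13.1% ± 0.528 of light fragments at 0 h and 12.1% ± 0.0411 at 4 h (SD, n = 2 each), and its change over both digests did not pass (exact p = 0.0195, adjusted p = 0.234). Most of that fall in the light digest lay in the bin X 21830001 to 21835000, at 13800 CPM at 0 h and 4920 at 4 h. The median bin of X lay between 0.6 and 0.636 of that of the autosomal arms in all 16 libraries.

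Neighbouring nucleosomes lay 176 ± 3.66 bp apart in the heavy and 179.5 ± 10.5 bp in the light digest (SD, n = 8 each), a difference within the spread (exact test, p = 0.25). The light 0 h libraries lay furthest apart, at 168.5 and 203.5 bp. Leaving out 1 library moved the difference of −3.25 bp to between −4.43 and −1 bp. From fragments of 120 to 180 bp the repeat length was 172 ± 2.12 and 174.7 ± 3.33 bp (exact test, p = 0.0469, adjusted p = 0.0938, and an exact p of 0.117 without pairs), which did not pass after adjustment. Over all fragments the later times lay −6.17 bp from 0 h, which did not pass (exact test, p = 0.199, adjusted p = 0.246), with −11.1 bp without light 0 h A and 0.444 bp without light 0 h B.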

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

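The tests of the dense site on X were chosen after its values were seen, and so was the comparison of X shares between digests.

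The share of fragments on X was not shown to change differently over time in the digests. Later over 0 h, its log2 ratio was −0.12 in the light digest and −0.01 in the heavy digest, a difference of 0.11 (exact p = 0.0469, adjusted p = 0.477 over 12 sequences), which does not pass. The dense site on X alone took 13800 ± 4530 CPM at light 0 h and 4920 ± 2010 at light 4 h (SD, n = 2 each), which makes up most of the fall of the light X share between these times.

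Fragments were placed on the Y heterochromatic scaffold, which entered the share of the scaffolds but was not compared on its own. It held 1550 fragments over the 16 libraries, from 12 to 368 per library, above the 3 counts that a count of 0 allows. Its density was 0.0154 of that of the autosomal arms, and 51.3% of the fragments lay in its 10 fullest kb. The bound of 3 does not cover repeated sequences of other chromosomes placed there, so these counts do not show that Y DNA was present.

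The lower density at X 21834001 to 21835000 after stimulation in the light digest was weighed against 3 technical explanations, and the response to stimulation remains among the open ones, untested by any independent sample. Copies of identical fragments remain open: with libraries thinned to equal depth, the log2 ratio of 4 h to 0 h over distinct fragments was −0.65 in A and −0.84 in B (mean −0.74), against −1.40 and −1.59 over all fragments, and distinct fragments run out at a site this dense (441 among 4142 in A at 0 h). A lower recovery of repeated DNA was checked on the X heterochromatic scaffold, with 94.6% of its fragments in 10 kb. Its share was higher at 4 h than at 0 h in both light replicates (log2 0.16 in A and 0.07 in B, mean 0.12). This also held over distinct fragments at equal depth (0.14 and 0.05). Over distinct fragments at unequal depth its mean share fell from 1.91% to 1.24%. The shares at equal depth argue against a lower recovery at that scaffold only, not of repeated DNA in general. On the scaffolds of 2L, 2R, 3L and 3R the shares were higher at 4 h in A and slightly lower in B. On that of 3L they went from 1.687% to 1.742% in A and from 1.551% to 1.468% in B. The spread between libraries of a group remains open: the SE from the bin's own spread was 0.73, against 0.21 after moderation, but it includes a difference between the letters, A over B in 8 of 8 groups by a mean log2 of 0.97 ± 0.56 (SD; exact sign-flip test, p = 0.00781), and the fall at 4 h was alike in both light replicates (−1.43 in A and −1.61 in B). It stays open because robust moderation, which keeps the spread of this bin, ended the call (adjusted p = 1).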

How the results depend on the processing

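Chosen after the data were seen were the block with robust moderation, fragment length as a term, the fits without the X site, the light 0 h or the 0 h libraries, 100 kb bins, robust moderation and the tests without pairs. The cause of a changed count was not tested, except where fewer fragments, bins or libraries entered by construction. Depth limits the comparisons with 0 h: the light 0 h libraries held a median of 10 and 12 fragments per bin.

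Bins differing between heavy and light digest (975) were 28 after thinning, 40 with fragment length as a term, 341 with fragments of 120 to 180 bp (61.0% of them higher, against 44.2%), 393 by limma trend, 1951 in 1 kb, 499 in 20 kb and 248 in 100 kb bins, and 2118 without the 0 h libraries. Other scalings gave 960 and 968. Without filter, light 4 h had 98 bins (2 higher, 96 lower) and both digests at 4 h 106. With at least 10 fragments in 8 libraries, each heavy comparison had 1 bin, light 0.5, 1 and 4 h had 5, 7 and 15 (the last 12 higher, 3 lower), and the difference between digests 1. In 1 kb bins, light 4 h had 1, both digests at 0.5 h 1 and at 4 h 2. With identical fragments counted once, light 0.5 h and 1 h had 1 each, both digests 1, 1 and 3, and the difference between digests 1. After thinning, heavy 1 h, each light time, both digests at 0.5 h and 1 h, and the difference between digests had 1 each. By limma trend the light counts were 188, 60 and 41, and those of both digests 2, 3 and 0. Library weights gave 1 at light 0.5 h, light 1 h, both digests at 0.5 h and the difference between digests, and a fit of a single digest gave 1 at light 0.5 h and 1 h. The counts at light 4 h and both digests at 4 h were each 0 in 20 kb bins, 100 kb bins, with fragments of 120 to 180 bp and with fragment length as a term, which gave 1 for both digests at 0.5 h. They were 1 and 0 without the X site and with robust moderation.

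The replicate letters were not shown to pair the samples by bins: 28 correlations of deviations between groups ran from −0.002 to 0.376 (median 0.028). The 2 over 0.1 were heavy 4 h with light 4 h (0.376) and light 1 h with light 4 h (0.153). Counting noise in shallow libraries lowers these correlations, so low values cannot show that the letters do not pair. The main fit leaves out any difference between the letters. The letters did differ: A exceeded B in 8 of 8 groups in the share of heterochromatic scaffolds and the density near the centromere of 2L, and B exceeded A in 8 of 8 in the share of 2R (exact sign-flip p = 0.00781 each). Also, 230 bins were higher in A in all 8 groups, and 124 in B, against 92.4 expected of each by chance. With a replicate block, the counts were 1 at each heavy time, 2 at light 0.5 h and 1 h, 1, 1 and 3 for both digests, 4 for the difference between digests and 1255 for heavy against light. The bin 3L 11035001 passed at heavy 4 h under the block (adjusted p = 0.045). At the X site the block gave −1.49 at light 4 h with an own SE of 0.41, and with robust moderation an adjusted p of 0.77.

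Leaving out 1 library at a time gave 290 to 1689 bins for heavy against light, 0 to 0 at each heavy time, 0 to 2, 0 to 3 and 0 to 5 at light 0.5, 1 and 4 h, 0 to 1, 0 to 1 and 0 to 3 for both digests, and 0 to 2 for the difference between digests. For heavy against light it gave a length difference of −17.7 to −14.7 bp, log2 ratios of 0.0134 to 0.0163 for arms, −0.148 to −0.108 for scaffolds and −2.53 to −2.29 for mitochondria, and a repeat length difference of −4.43 to −1 bp. For later times it gave −6.56 to 0.667 bp, −0.00803 to −0.00362, 0.0282 to 0.0725, 0.208 to 0.596 and −11.1 to 0.444 bp in the same order. The mitochondrial change over time passed without heavy 4 h B (0.528, exact test, adjusted p = 0.0469), and had an exact p of 0.0434 (adjusted 0.13) without series. The heterochromatic difference between digests no longer passed with identical fragments counted once (−0.105, exact test, adjusted p = 0.0781) or without pairs (−0.122, adjusted p = 0.11). The repeat length difference with fragments of 120 to 180 bp was −2.69 bp (unadjusted exact p = 0.0469, adjusted 0.0938). Of 866 values of named bins under alternatives, 774 kept their side of the threshold, 65 lost and 27 gained a call, and 0 reversed. The GC correction, count-based tests and gene lists were not run. A repeat length is not given here for chromosome 4 and the scaffolds.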

Other observations

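The tests of neighbouring bins, short fragments and replicate letters were chosen after the calls were seen, each before its own result was known. The values in the next paragraph were noticed in the data.

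Fragment density differed between chromosomes in all 16 libraries. No library of undigested DNA was among them, so the copy number of a region and its occupancy cannot be told apart in these densities. The X chromosome had 0.612 ± 0.0105 of the median density of the autosomal arms, and 3L had 0.881 ± 0.0209 (SD, n = 16 each). Chromosome 4 had 0.77 in the heavy and 0.921 in the light digest. Within arms, 2L 8000001 to 9000000 lay 0.52 above its arm on the log2 scale, or 1.44-fold, in 16 of 16 libraries, and its neighbour 2L 7000001 to 8000000 lay at −0.37 in 16 of 16. On 3L, 22000001 to 23000000 lay at 0.46 and 11000001 to 12000000 at −0.36. Mitochondrial fragments were shorter than those of the arms in 16 of 16 libraries, by −35.2 ± 10 bp (permutation test over 65536 sign flips, p = 3.1e-05, the smallest they can give), with medians of 87.2 ± 6.73 bp in the heavy and 85.9 ± 6.6 bp in the light digest (SD, n = 8 each). Chromosome 4 fragments were shorter by −8.12 ± 3.34 bp in 16 of 16 libraries (permutation test, p = 3.1e-05).

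Bins lower in the heavy digest may be regions where short, partly protected fragments are common. In the light digest alone, 50 to 100 bp fragments made up a median of 31.0% ± 7.57 of such bins, 23.5% ± 5.46 of uncalled bins and 15.5% ± 3.7 of bins higher in the heavy digest (SD, n = 8 libraries), and the order held in 8 of 8 light libraries for lower against uncalled bins. The light libraries also entered the calls, so this remains a hypothesis. Of 100 splits of the libraries within times, drawn from 648 distinct ones, 1, the real one, gave as many as 975 bins. The highest other gave 71. The other splits mix heavy and light libraries in a group, which widens the spread and can lower their counts. A grouping by chance was therefore seen in no other drawn split, but it is not excluded.

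For the times, the 18 splits per comparison are too few for a share under 0.05. At 0.5 and 1 h the real split called 0 bins, so 18 of 18 splits gave as many by definition and the comparison says nothing (highest other 3 and 1). At 4 h, 11 of 18 splits gave as many (real 1, highest other 379). The splits with 379 and 336 bins at 4 h set replicate A of 4 h against replicate B of 4 h in both digests, which points to a structure of the samples. A candidate explanation is that digestion went less far in replicate A than in B at 4 h: across bins, A minus B at 4 h correlated with heavy minus light at the other times (r = −0.319, against 0.011, 0.025 and −0.013 for A minus B at 0, 0.5 and 1 h), and A minus B at 4 h correlated between the digests (r = 0.354). The light libraries of the earlier times were shallower than those of 4 h, and counting noise lowers r. These values therefore do not confine a difference between the letters to 4 h. Over all times, A exceeded B in 8 of 8 groups in the shares of chromosome 4 and the heterochromatic scaffolds (exact sign-flip p = 0.00781 for each). The prediction set before the result asked for an r over 0.1 or under −0.1, and this was met. Longer fragments in A, a further condition, were not part of that prediction. On the arms the median at 4 h was 110 bp in A and 113 bp in B of the heavy digest, and 124 and 126 bp in the light digest. On chromosome 4 it was 105 and 104 bp, and 118 and 110 bp. Over the 8 groups, A had the longer arm median in 6 and B in the 2 of 4 h (mean 7.75 ± 8.65 bp, SD, exact sign-flip test, p = 0.0312). The explanation stays open. Bins are not independent replicates, and 1 library per letter and digest gives no spread for these lengths.

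Broad changes after stimulation, too small to be called in a single bin, remain open. The log2 fold changes of neighbouring bins at 4 h correlated with r = 0.038 over both digests, against 0.202 for heavy against light. The highest of the other 17 splits gave 0.276, but that split follows the difference between replicates A and B at 4 h, so the bound set for this test, that highest split, was wrong and broad changes cannot be told apart from this structure.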
